A study of Chordodes fukuii and Tenodera angustipennis with 34 samples.

How the data were processed

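RNA sequencing data of 34 libraries were used. There were 19 libraries from whole bodies of the nematomorph Chordodes fukuii and 15 from whole brains of the mantid Tenodera angustipennis. Per the labels each library is 1 individual. Stage or state, sampling year, worm sex, worm weight and the host of each worm were taken from the labels. The worm labelled after replicate 4 came from a host whose brain is labelled during, and both labels were kept.

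The deposited counts are raw read counts per gene model. Per the labels reads were processed with HISAT2 2.1.0 and featureCounts 1.5.1, on reference sequences assembled without a genome. The deposited TPM values (length-scaled transcript abundance) equal the counts divided by the summed exon length of each gene model and scaled to the same sum in every library, within 1e-06 for 100% of non-zero values, so they are not an independent measurement. The deposited gene models numbered 76458 for the worm and 195386 for the mantid, of which 26607 and 28499 were in the count tables. The filter that chose them is not stated. Gene models carry identifiers made of 2 numbers joined by a point and no gene names, and no reference genome was at hand. Tests of gene lists, planned for named genes, were therefore not run, and no function is given for any gene.

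Counts were analysed in R 4.3.3 with edgeR 4.0.16. Each species was fitted once, over all of its libraries, with a coefficient per stage or state and sampling year as an additive factor. Genes were filtered with filterByExpr (min.count 10, min.total.count 15) and libraries scaled with TMM factors. Quasi-likelihood F-tests were made for 4 worm and 4 mantid comparisons. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested in a comparison. The 1 comparison beyond pairs of stages in the worm set the during stage against the mean of before and after. In the mantid the mean of both infected states was set against uninfected. Standard errors of log2 fold changes were derived from the test statistic. A further worm fit with a coefficient per stage and year tested whether the during against before difference differed between 2017 and 2018.

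The design, the tests, the settings to be varied and the rule for naming genes were fixed before the data were examined. By that rule, for identifiers without names, each pairwise comparison names at most 2 rising and 2 falling genes. These are the ones with the smallest p among genes with an adjusted p under 0.05, an absolute log2 fold change of at least 1 and a mean TPM of at least 1. A gene that qualified in 2 comparisons was named in both. Numbers of decimals follow 3 significant digits.

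The share of variance by state was computed from log2 CPM (TMM, prior count 2) after year, with 100000 permutations of state labels within years, 1-sided. Worm weights were compared by exact permutation tests, 2-sided, over all worms of 2 stages. Shares of genes called per class of gene model carry exact binomial 95% intervals. Similarity of libraries was measured by Spearman correlation over tested genes, and by principal components of log2 CPM. Total counts, genes with a non-zero count and a floor of 3 counts were computed per library. That floor lay between 0.137 and 0.561 CPM.

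The fit was tested on simulated data. Negative binomial counts with the estimated dispersions, library sizes and design were drawn, with 100 genes changed 4-fold and 100 changed 16-fold. In the worm during against before comparison edgeR called 1 and 16 of them, with 0 false calls. DESeq2 called 17 and 50 with 237 false calls, and limma 2 and 26 with 3 false calls. The common dispersion was 2.2 in the worm and 1.01 in the mantid. Simulated libraries without change gave the covariance to be had from libraries shared between comparisons.

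The settings varied were DESeq2 1.42.0, limma 3.58.1 on log2(TPM + 1), RLE scaling, no filter or a mean CPM of at least 1, a minimum log2 fold change of 1, no year term, single years, only the groups compared and each library left out in turn. For the worm they were also summed siblings, only worms alone in their host, no male, worm weight as covariate, only worms whose host brain was sequenced, and 20 draws of 4 before and 5 during libraries. Alternatives chosen after seeing the data left out worm before libraries 8 and 9, added the counts of identifiers that share the number before the point, or did both, and left out mantid uninfected library 3 and during library 3. Also added after seeing the data were exact tests of worm weight with stages permuted within years, with and without siblings averaged, the numbers of called genes at 0 in a whole stage without before libraries 8 and 9, and a count of genes at a CPM of at least 100 in every other during library that a library has at under 1% of their lowest value. Other groupings of the same libraries were refitted in 100 random splits per comparison, and in 80 for the during stage against the mean of the others. Figures were drawn with matplotlib 3.10.9.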

Results

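Transcript levels were measured by RNA sequencing in a horsehair worm, Chordodes fukuii, and in the brain of its host, the mantid Tenodera angustipennis. Horsehair worms (Nematomorpha) grow inside arthropods and leave them in water, and infected hosts enter water, which is the behaviour that the study calls manipulation. Each worm library was made from a whole body, and each mantid library from a whole brain. The worms were sampled before (9 libraries), during (6 libraries) and after (4 libraries) manipulation. The brains came from uninfected mantids (6 libraries) and from infected mantids before (4 libraries) or during (5 libraries) manipulation. Sampling spread over 3 years, 2017 to 2019, and no after worm was from 2019 and no infected before brain from 2018. The worm before group held the 1 male worm and 2 pairs of worms that shared a host.

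Total counts per library ranged from 12090845 to 21866271 in the before worms, from 14366630 to 18852267 in the during worms and from 12313322 to 20073408 in the after worms. In the brains they ranged from 5344118 to 18006911 in uninfected, from 7335903 to 12974553 in before and from 9972303 to 13137963 in during mantids. The count tables held 26607 worm and 28499 mantid gene models, and 20538 and 16302 of them passed the filter on low counts. The gene models carry assembly identifiers and no gene names, so the genes below are given by identifier and no statement about their function is made.

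The worm libraries fell into 2 sets that only partly followed the stages. All 6 during libraries correlated closely with each other (median Spearman 0.882, over tested genes) and hardly with the 4 after libraries (median 0.22). The after libraries in turn resembled 7 of the before libraries (median 0.797). Before libraries 8 and 9 were the exception, since their median correlations with the during libraries were 0.876 and 0.724, against 0.216 and 0.18 with the other before libraries. Library 8 came from the same host as before library 7, and the correlation between these siblings was 0.216. Library 9 was from the only male. The first principal component, which separated the 2 sets, held 66.2% of the variance. Genes that were higher in during worms, called without libraries 8 and 9, took 58 to 65% of the counts in during libraries, 3.32 to 9.03% in the other 7 before libraries, 56.5% in library 8 and 23% in library 9. The gene counts of the worm comparisons were therefore also computed without these 2 libraries. Without them the 2 sets coincide with during against the other stages, so those counts cannot separate stage from set.

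**Figure D1:**
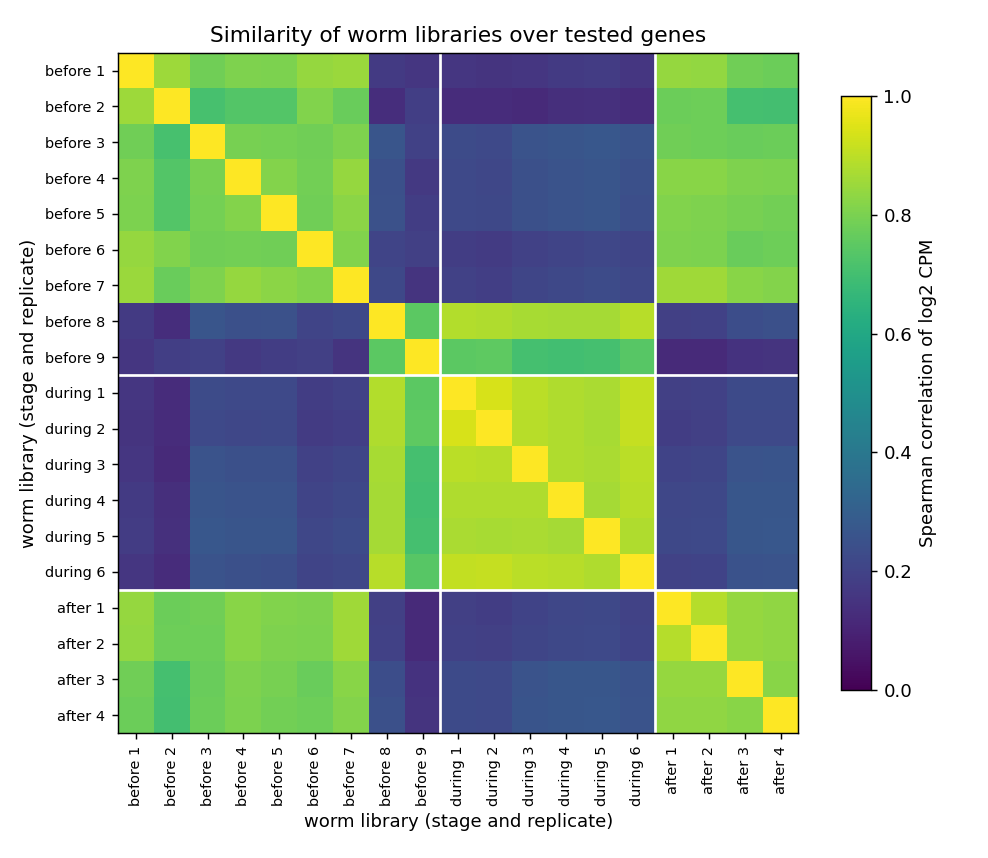
Spearman correlation of log2 CPM over tested genes between all pairs of the 19 worm libraries, ordered by stage and replicate, with white lines between stages. Before libraries 8 and 9 share high correlations with the 6 during libraries (medians 0.876 and 0.724) and low ones with the other before and the after libraries.

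The comparison of during with before worms addressed the onset of manipulation in the parasite. The gene with the smallest p that rose was Cluster-44093.0, a model of 932 bases, at 0.36 ± 0.523 TPM before (SD, n = 9) and 3200 ± 1310 TPM during manipulation (SD, n = 6). Its lowest during library was at 1540 TPM and its highest before library at 1.39 TPM. Cluster-34963.2 rose from 0.0306 ± 0.0483 TPM (SD, n = 9) to 83.4 ± 68.7 TPM (SD, n = 6), with 5 of the before libraries at a count of 0. Among falling genes, Cluster-44010.0 went from 105 ± 75 TPM to 4.36 ± 1.67 TPM and Cluster-33132.2 from 108 ± 63.8 TPM to 7.17 ± 2.4 TPM (SD, n = 9 and n = 6). The log2 fold changes of these genes were 12.8 ± 0.995 and 11.2 ± 1.11 for the rising pair and -5 ± 0.55 and -4.3 ± 0.482 for the falling pair (± SE). For all of these genes the stages did not overlap, and before libraries 8 and 9 lay with the other before libraries, although these genes were chosen in a fit that used their labels.

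In edgeR's quasi-likelihood test with sampling year in the model, 13055 of 20538 genes (63.6%) passed a Benjamini-Hochberg adjusted p of 0.05, of which 5640 were higher and 7415 lower during manipulation. The 4 named genes had adjusted p of 2.7e-06, 6.34e-05, 0.000144 and 0.000144 in this test. Of the lower genes, 2962 (39.9%) had a count of 0 in every during library, and 105 of the higher genes (1.86%) had a count of 0 in every before library. Without before libraries 8 and 9, 6484 genes were higher and 8211 lower, of which 1675 (25.8%) and 3026 (36.9%) had a count of 0 in every library of the other stage. Without sampling year in the model, 1542 were higher and 7374 lower. When the counts of gene identifiers sharing the number before the point were added together, 1898 of 10083 such sums were higher and 2287 lower. With only the worms whose host brain was sequenced, edgeR called 0 genes, with 1972 at an unadjusted p under 0.05. These worms include before library 9 and the summed siblings 7 and 8. The 4 named genes were at an adjusted p of 0.212 in this edgeR test. Over 33 alternatives, this one included, the log2 fold changes of the rising genes lay at 9.44 to 14.8 and 4.61 to 12.8. Those of the falling genes lay at -5.48 to -3.3 and -5.04 to -3.75.

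Within single years, the same comparison called 12113 genes among the 2017 libraries (2 before, 2 during) and 8781 among the 2018 libraries (3 before, 3 during). Of the 3 before worms of 2018, 2 shared a host, and 2019 held 1 during library. The direct test of whether the during against before difference differed between 2017 and 2018 called 0 genes by edgeR. It had 604 genes at an unadjusted p under 0.05, fewer than the 1027 due to chance alone. With so few worms per year, the 0 does not show that the years were alike. In that fit, which has a coefficient per stage and year, edgeR called 0 genes within 2017 (7517 at an unadjusted p under 0.05, smallest adjusted p 0.0895), 7282 within 2018 and 1 within 2019 (1153 at an unadjusted p under 0.05, where 1027 would be due to chance alone), the year of before libraries 8 and 9. The log2 fold changes of the 2 years correlated at 0.87 across genes, which are not independent replicates.

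The comparison of after with during worms addressed the end of manipulation. Cluster-36324.1 rose from 0.0356 ± 0.0551 TPM (SD, n = 6) to 909 ± 554 TPM (SD, n = 4), and Cluster-44601.0 from 0.0819 ± 0.101 TPM to 273 ± 183 TPM (SD, n = 6 and n = 4). The lowest after libraries were at 93.2 and 110 TPM for these genes, and both were also near 0 before manipulation, at 0.242 ± 0.542 and 0.194 ± 0.364 TPM (SD, n = 9). The falling genes with the smallest p were the same as those that rose at the onset. Cluster-44093.0 returned to 0.308 ± 0.218 TPM and Cluster-34963.2 to 0.0285 ± 0.0195 TPM (SD, n = 4). By edgeR the log2 fold changes were 14.4 ± 1.62 and 11.9 ± 1.49 for the rising genes (adjusted p 0.000466 and 0.000613) and -13.5 ± 1.51 and -10.9 ± 1.61 for the falling genes (± SE; adjusted p 0.000466 and 0.000613). With counts added over identifiers that share a number, the falls of the latter were -3.31 ± 1.33 and -3.74 ± 1.93 and did not pass the threshold (adjusted p 0.0659 and 0.146).

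Of 20538 genes, 11763 (57.3%) were called by edgeR between after and during worms, 6222 higher and 5541 lower in after worms. Of the higher genes 2425 (39%) had a count of 0 in every during library, and of the lower genes 2512 (45.3%) had a count of 0 in every after library. Without before libraries 8 and 9, which belong to neither group but to the same fit, 7170 of 19774 genes were higher and 6199 lower. Within years, 11316 genes were called in 2017 (2 after, 2 during) and 7392 in 2018 (2 after, 3 during), and 7716 were called with worm weight as a covariate. Added counts gave 1533 higher and 1541 lower sums.

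**Figure D2:**
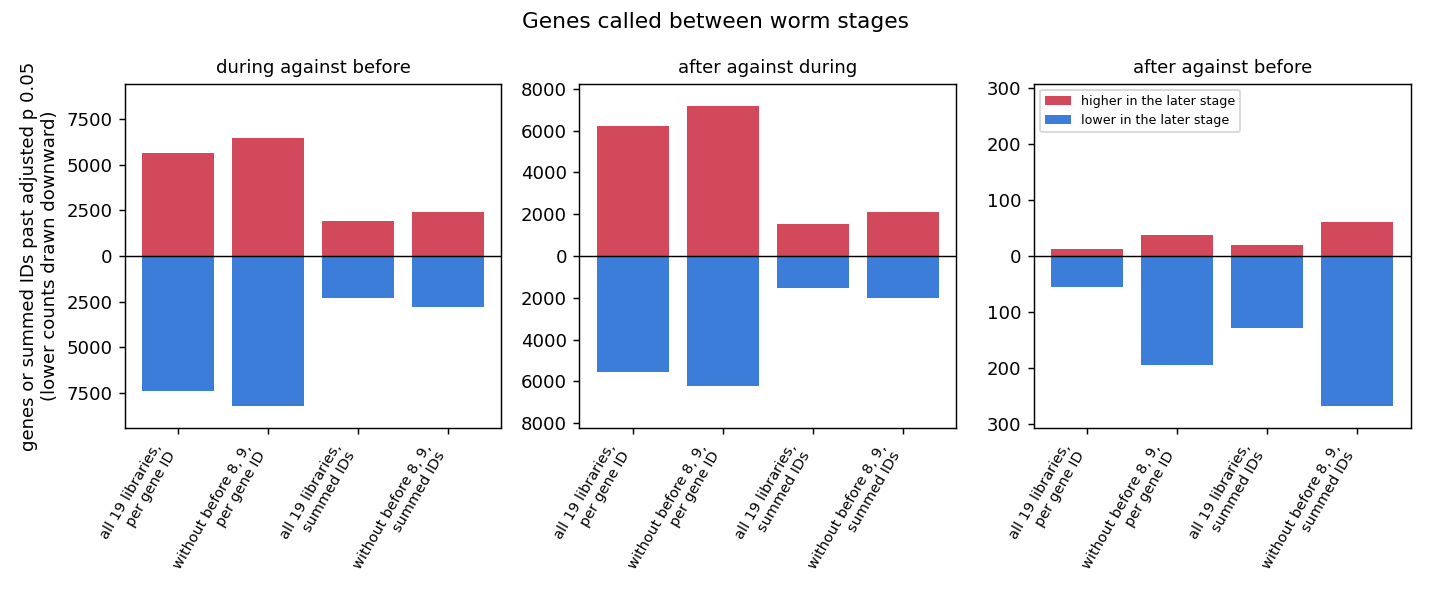
Genes, or sums over gene identifiers sharing a number, past an adjusted p of 0.05 in edgeR between worm stages, with higher counts drawn upward and lower counts downward, for all 19 libraries and without before libraries 8 and 9; the vertical scale differs between panels. After against before gave 12 higher and 55 lower genes, against 5640 and 7415 for during against before.

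Of the genes called in both comparisons, 4715 rose and then fell, and 5701 fell and then rose, while 2 rose in both steps and 13 fell in both. Without before libraries 8 and 9 the numbers were 5676 and 6706, and with counts added over identifiers that share a number they were 1242 and 1254 of 10083 sums. Independent lists of the sizes in all libraries would share 1522 genes that rose and then fell and 2246 that fell and then rose. The during libraries enter both comparisons, which by itself makes the fold changes run opposite. The covariance of the log2 fold changes was -36.1, against -1.3 to -1.38 in 3 sets of simulated libraries without any change, in which 0 genes were called in both. In further fits the 6 during libraries were divided in every way into 2 sets of 3. For each comparison 1 set was used, so that the comparisons shared no during library. Each division was read with its sets in both orders, which gave 20 values that are not independent. Over these a median of 3266 genes rose and then fell (lowest 1012, highest 3573) and the covariance lay between -35.4 and -33.8. The division removes the effect of shared during libraries only. All during libraries lie in the same set of libraries, so it cannot separate a course over stages from a difference between the sets. Cluster-44093.0 and Cluster-34963.2 are examples of the rising and falling course.

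The direct test of the during stage against the mean of before and after called 14150 of 20538 genes (68.9%) by edgeR, 6683 higher and 7467 lower. Without before libraries 8 and 9 the counts were 6909 and 8159, and with added counts 2260 sums were higher and 2137 lower. Stage accounted for 52.1% of the variance between worm libraries after year, and year for 8.46% (permutation test of stages within years, 1-sided, 100000 resamples, p = 0.00054). The during libraries all lie in the same set of libraries and the after libraries in the other, so this share cannot separate stage from set.

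The comparison of after with before worms addressed the net change over the period. Cluster-45450.0 rose from 0.714 ± 0.7 TPM before (SD, n = 9) to 6530 ± 2000 TPM after manipulation (SD, n = 4) and lay at 13.9 ± 21 TPM in during worms (SD, n = 6). Cluster-37778.1 rose from 0.0831 ± 0.16 TPM (SD, n = 9) to 581 ± 180 TPM (SD, n = 4). Cluster-28473.1 fell from 2570 ± 1070 TPM (SD, n = 9) through 33.5 ± 43.4 TPM during manipulation (SD, n = 6) to 20.6 ± 4.53 TPM (SD, n = 4). Cluster-40670.0 fell in steps, from 82.7 ± 54.2 TPM (SD, n = 9) to 5.53 ± 1.63 TPM (SD, n = 6) and 0.351 ± 0.285 TPM (SD, n = 4). Its difference between after and before worms did not pass the threshold under 1 of 28 alternatives. Before libraries 8 and 9 lay within the range of the other before libraries for these genes, except that library 8 was below the others for Cluster-28473.1, of which the lowest was at 1710 TPM.

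By edgeR the log2 fold changes of these genes, in the order given, were 12.3 ± 1.2, 12 ± 1.53, -7.43 ± 0.966 and -8.63 ± 1.04 (± SE; adjusted p 9.94e-05, 0.00187, 0.00193 and 0.00132). In all, 67 of 20538 genes were called, 12 higher and 55 lower, and without before libraries 8 and 9 there were 231, of which 37 were higher and 194 lower and which included all of the 67. The count also moved when single libraries were left out, to 18, 13, 9 and 8 without after libraries 1, 2, 3 and 4, to 32, 40, 37 and 39 without before libraries 1, 3, 4 and 5, and to 102 without before library 9. DESeq2 called 1670 genes and limma 168. Worm weight could not be separated from this comparison, because the weights of before worms (0.333 ± 0.0949 g, SD, n = 9, highest 0.49 g) and after worms (0.67 ± 0.0906 g, SD, n = 4, lowest 0.59 g) did not overlap, and 5 genes were called with weight as a covariate.

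**Figure D3:**
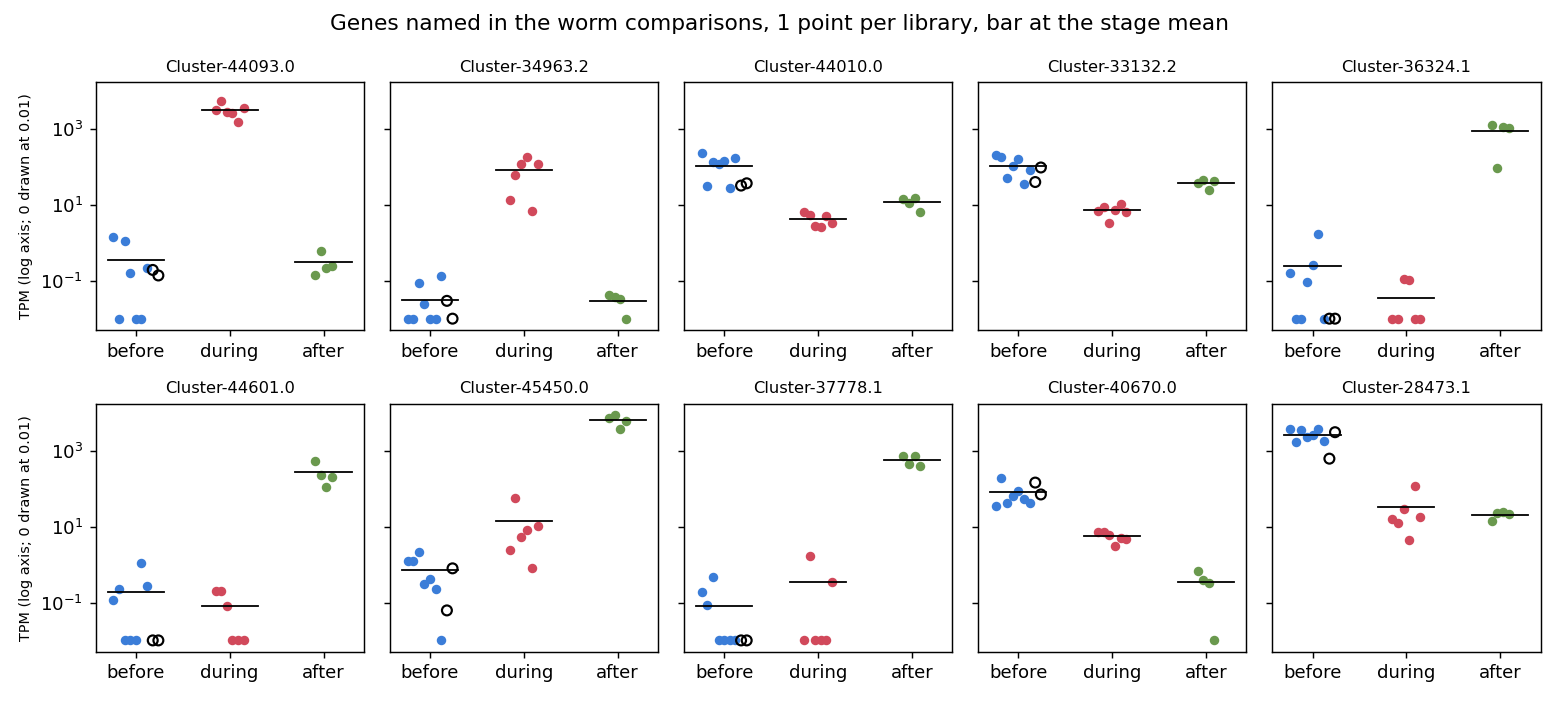
TPM on a log axis (0 drawn at 0.01) of the 10 genes named in the worm comparisons, with 1 point per library by stage, open circles for before libraries 8 and 9 and a bar at the stage mean. Cluster-44093.0 is at 1540 TPM or more in every during library and at 1.39 TPM or less in every before library, and Cluster-45450.0 reaches 6530 TPM on average in after worms.

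During worms weighed 0.512 ± 0.109 g (SD, n = 6), which was 0.178 g more than before worms (exact permutation test, 2-sided, p = 0.00679, adjusted over 3 comparisons 0.0102). After worms weighed 0.158 g more than during worms (exact permutation test, p = 0.0619, adjusted 0.0619) and 0.337 g more than before worms (exact permutation test, p = 0.0014, adjusted 0.0042). With stages permuted within years and the difference adjusted for year, during worms were 0.176 g heavier than before worms (exact permutation test, 2-sided, 600 arrangements, p = 0.0217, adjusted 0.0326). After worms were 0.157 g heavier than during worms (exact permutation test, 60 arrangements, p = 0.15, adjusted 0.15) and 0.324 g heavier than before worms (exact permutation test, 60 arrangements, p = 0.0167, the smallest they can give, adjusted 0.0326). With siblings of 1 host averaged as well, the differences from before worms did not pass the threshold (exact permutation tests, p = 0.0417 for during and 0.0556 for after, which is the smallest its 36 arrangements can give, adjusted 0.0834 for both).

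Gene models with 1 assembled transcript were called higher in during worms more often than models with 2 or more, at 33.3% of 7297 (exact binomial 95% interval 32.3 to 34.4%) against 24.2% of 13241 (23.5 to 25%). For lower genes the order was the opposite, at 34.5% (33.4 to 35.6%) against 37% (36.2 to 37.8%). Of 4 classes by model length, the shortest was called lower in 41.4% (40 to 42.7%) and the longest in 31.5% (30.3 to 32.8%). Genes lower in after than in before worms came mostly from the highest of 4 classes by mean expression, which held 51 of the 55. The intervals treat genes as independent, which they are not.

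In the mantid brain, the comparison of during with before addressed manipulation itself. No gene passed the threshold: 0 of 16302 were called by edgeR, 72 had an unadjusted p under 0.05 where 815 would be due to chance alone, and the smallest adjusted p was 1. DESeq2 called 205 genes, 159 higher and 46 lower, and limma on log2(TPM + 1) called 0. The median standard error of a log2 fold change was 1.29, so that only large changes could have passed. In simulated libraries with the spread of these brains, the edgeR test called 8 of 100 genes changed 4-fold and 39 of 100 changed 16-fold, and DESeq2 called 61 of the unchanged genes.

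Infection without manipulation, before against uninfected, gave 0 genes by edgeR (130 at an unadjusted p under 0.05, smallest adjusted p 1), 192 by DESeq2 and 3 by limma, and 3 by edgeR without before library 1. Infection with manipulation, during against uninfected, gave 0 by edgeR (244 at an unadjusted p under 0.05, smallest adjusted p 0.184), 125 by DESeq2 and 4 by limma, and 3 by edgeR without during library 5. For all infected against uninfected brains the counts were 0 by edgeR (196 at an unadjusted p under 0.05, smallest adjusted p 0.464), 150 by DESeq2 and 3 by limma, and edgeR called 3 without before library 1 and 3 without during library 5. The log2 fold changes of the first and second of these comparisons had a covariance of 0.712, against 0.602 to 0.65 in simulated libraries without change that shared the same uninfected controls.

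State accounted for 8.31% of the variance between brain libraries after year (permutation test within years, 1-sided, 100000 resamples, p = 0.94) and year for 25.1%. Libraries differed in the number of genes detected, from 20761 to 23932 in 2017, from 10123 to 21471 in 2018 and from 16109 to 19338 in 2019. Uninfected library 3 had 49.8% of the tested genes at a count of 0 and during library 3 had 36.5%. A single gene model held 25.5% of the counts of uninfected library 3, 15.3% of before library 4 and 14.9% of during library 5. Without uninfected library 3 and during library 3, each of the 4 brain comparisons gave 0 genes by edgeR, with 110, 155, 252 and 227 at an unadjusted p under 0.05 in the order above.

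**Figure D4:**
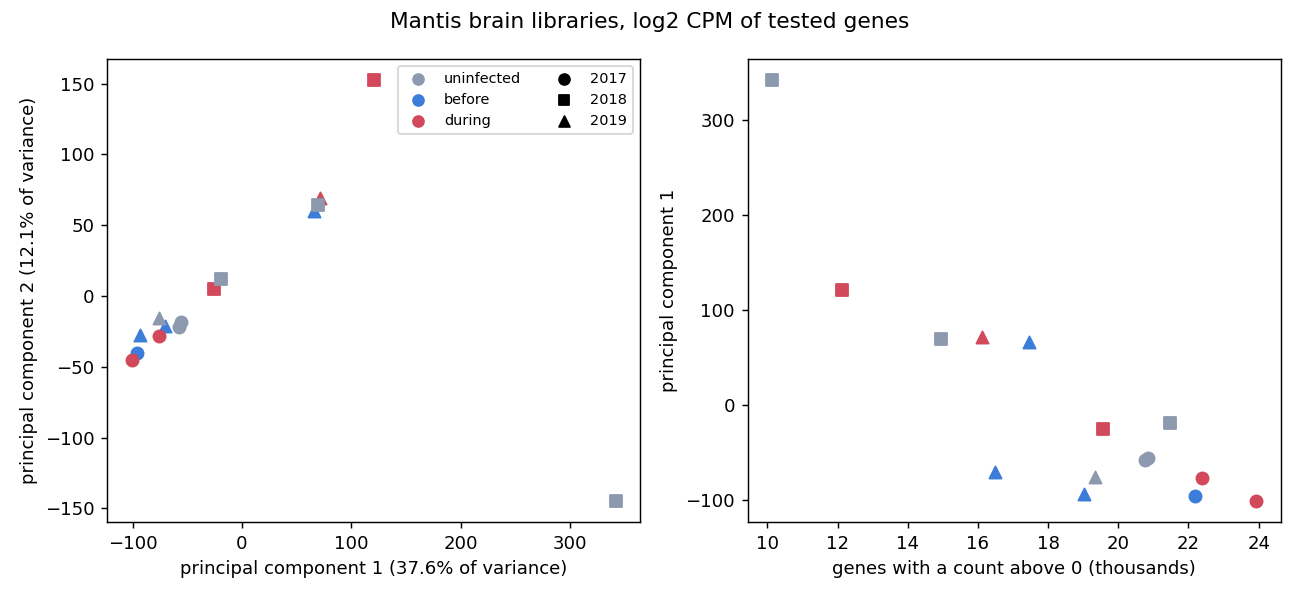
Mantid brain libraries by their first 2 principal components of log2 CPM over tested genes (left) and the first component against the number of genes detected (right, axis in kilo-genes), coloured by state and marked by sampling year. Uninfected library 3, with 10123 genes detected, lies apart, and the states overlap.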

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

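The tests of the worm libraries that form 2 sets were chosen after the result was seen, including the bounds that decided them, while the tests of the brain comparisons and the random splits were chosen before.

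Before libraries 8 and 9 grouped with the 6 during libraries and apart from the other 11 worm libraries. The lower of their 2 median correlations with during libraries, 0.724, restates this pattern and was no separate test. The medians of libraries 8 and 9 with the other before libraries were 0.216 and 0.18, where those 7 libraries correlated at 0.708 to 0.852 with each other. With the labels as given, these values argue against stage alone. At called sums of counts, library 8 lay nearer the during mean in 82.2% and library 9 in 60%, where left-out during libraries lay between 85.2 and 91.7% and the other 7 before libraries between 12.3 and 27.4%, and over sums expressed in all libraries the values were 76.5 and 42.5%, against 83.5 to 92.6% and 14.1 to 28.6%. A wrong stage label cannot be told apart from other causes for either library. Library 8 lacked 1 of 1188 genes and 2 of 1346 sums abundant in every during library (0 to 1 of each in left-out during libraries). It weighed 0.32 g (lightest during worm 0.37 g). Library 9 lacked 97 genes and 75 sums but was the only male. The host brains of both worms are also labelled before. Before library 7, from the host of library 8, had median correlations of 0.819 with the other before libraries than 8 and 9 and 0.211 with during libraries. A candidate explanation is that worms of 2 divergent sequence types were each counted on their own gene models: 1532 of 1987 identifier pairs changed in opposite directions, their levels correlated at 0.585 across pairs (random pairs -0.102 to 0.104), but partners that changed in the same direction also correlated, at 0.533, and assemblers can split models by expression, so switching between gene copies stays open.

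No gene was called by edgeR in the 4 brain comparisons, with 72, 130, 244 and 196 at an unadjusted p under 0.05 and 205, 192, 125 and 150 by DESeq2. Without uninfected library 3 and during library 3, the 2 libraries with few detected genes, at most 0 genes were called. This cannot decide whether their spread was the cause, because the refit had fewer libraries and low power. Too little power may account for the 0 calls, since 8 of 100 genes simulated with a 4-fold change were called in during against before. A biological absence of change stays open and was not tested.

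In random splits of the same libraries, only the real split gave as many calls in the worm comparisons that involve the during stage. The labels were moved across years and between worms of 1 host, which are not exchangeable. Any other split of the after and during worms mixes the 2 sets of libraries, so the splits cannot separate stage from set. In during against before, 1 of 100 splits, the real one with 13055 genes, gave as many, and the highest other gave 0. In after against during it was 1 of 100, with 11763 against 2811. For during against the mean of before and after it was 1 of 80, with 14150 against 1. In after against before 2 of 100 splits gave as many as the 67 genes, with 94 in the highest other. In the brains the splits say nothing about chance, because with 0 genes in the real split any split gives as many, 100 of 100 in each comparison. The highest others gave 0, 107, 0 and 5 in the order during against before, before against uninfected, during against uninfected and infected against uninfected.

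In 14 of 69 tests the gap of the most extreme library to its nearest neighbour was large relative to the range of its group. At 1 in 20 about 3.5 would be due to chance, for independent and normally distributed values. The tests share libraries, and 6 of the 14 were in the TPM of named genes, so 3.5 is no exact expectation. Worm before library 4 had a total of 21.9 M counts (mega), with the nearest library at 16.1 M. Worm before library 8 had 56.5% of its counts in genes higher in during worms (nearest 23%) and 21.7% in genes lower in during worms (nearest 56%). Worm after library 4 had a median correlation with its group of 0.834 (nearest 0.841), a small gap in a group of narrow range. Mantid during library 5 had 14.9% of its counts in 1 gene model (nearest 3.57%), and uninfected library 3 had 25.5% (nearest 5.11%). Median correlations with the own group were 0.751 in mantid before library 4 (nearest 0.887) and 0.639 in uninfected library 3 (nearest 0.818). Among named genes, Cluster-28473.1 stood at 120 TPM in during library 5 (nearest 29.3), and Cluster-45450.0 at 56.2 TPM in during library 2 (nearest 10.6). Cluster-37778.1 was at 1.69 TPM in during library 2 (nearest 0.346) and at 0.475 TPM in before library 3 (nearest 0.186). Before library 6 had Cluster-36324.1 at 1.67 TPM (nearest 0.255) and Cluster-44601.0 at 1.12 TPM (nearest 0.281).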

How the results depend on the processing

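The alternatives without worm before libraries 8 and 9, without mantid uninfected library 3 and during library 3, with counts added over identifiers sharing a number, and with worm weights permuted within years were chosen after the result was seen. No paired analysis was possible because replicate numbers follow the order of deposition and pair no libraries across groups. Every other setting chosen before gave a fit. Restricting the fit to the groups compared is the same fit for during against the mean of before and after and for infected against uninfected. Over 352 values of the named genes under alternatives, 343 passed the threshold, 9 did not and 0 reversed. These genes were chosen by their p in the same libraries, which most alternatives reuse, so these values are no independent check. The cause of the changes below was not tested, except that fewer libraries or fewer sums were tested where stated.

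After against before called 67 worm genes, but 1670 with DESeq2, 168 with limma, 39 with only the groups compared, 102 without the male, 113 with worms alone in their host, 5 with weight as covariate, 231 without before libraries 8 and 9, 148 with added counts and 328 with both. With single libraries left out it ranged from 8 (without after library 4) to 102 (without before library 9). After against during called 11763, but 7716 with weight, 7392 within 2018, 3074 with added counts and 4095 with both, and 9537 to 11466 with single libraries left out. During against before called 13055, but 0 by edgeR with only worms whose host brain was sequenced (1972 at an unadjusted p under 0.05), 4185 with added counts, 5195 with both and a median of 495 over 20 draws of fewer libraries. The 4 draws with neither before library 8 nor 9 gave 9643 to 10997, and the 16 others 0 to 7399. Leaving out single libraries gave 11605 to 13704. During against the mean of the others called 14150, but 4397 with added counts and 5211 with both, and 12830 to 14563 with single libraries left out. Genes that rose and fell numbered 1242 with added counts and 1677 with both, and those that fell and rose 1254 and 1762. Adding counts leaves 10083 sums to test. With siblings averaged and stages permuted within years, the weight differences from before worms were 0.171 g for during and 0.328 g for after worms and no longer passed the threshold (exact permutation tests, adjusted p 0.0834 for both), with fewer values in the test.

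In the brains, where edgeR called 0, DESeq2 called 205 in during against before, 192 in before against uninfected, 125 in during against uninfected and 150 in infected against uninfected. limma called 0, 3, 4 and 3, and edgeR without a filter 1 in during against uninfected. With single libraries left out the counts were 0 to 0, 0 to 3 (3 without before library 1), 0 to 3 (3 without during library 5) and 0 to 3 (before library 1 or during library 5). The share of variance by state was 39.3 to 71.8% in worms and 7.81 to 9.53% in brains. Depth limits genes under the floor of 3 counts.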

Other observations

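The tests of counts added over identifiers that share a number were chosen after the result was seen. Added counts brought the 2 sets of worm libraries closer. The median Spearman correlation of during libraries with the 7 before libraries other than 8 and 9 was 0.213 per gene identifier and 0.737 with added counts, and with after libraries 0.22 and 0.752. With added counts the median with during libraries was 0.911 for library 8 but 0.713 for library 9, below that of those 7 libraries. Correlations within the during and within the 7 before libraries rose as well, from 0.882 to 0.93 and from 0.801 to 0.883. Adding counts over randomly chosen identifiers was not tried as a reference. The share of variance by stage after year was 39.3% with added counts (permutation test, 1-sided, p = 4e-05). The during libraries all lie in the same set and the after libraries in the other, so this share cannot separate stage from set.

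Opposite identifier pairs numbered 1532 of 1987 (77.1%), where random permutations of the directions gave 902 to 1047. Assemblers can split models by expression, which could by itself yield opposite partners, so the excess over permutations does not tell its cause. The partners shared an assembly component name in 86.9% of opposite pairs and in 70.5% of same-direction pairs. Their levels lay within 2-fold of each other in 51% of opposite pairs, a share that was not computed for random or same-direction pairs.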
